A study of Mus musculus with 9 samples.

How the data were processed

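RNA sequencing was done on 9 libraries of primary cells from the spinal meninges of mice, labelled as fibroblasts with spinal cord as the tissue. Per the labels, 3 libraries came from each of 3 segments called C, T and L, and the letters are not spelled out there. The cells are described as freshly collected and not treated, RNA was extracted with TRIzol, and libraries were made from total RNA with a kit that keeps strand, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The description of L replicate 3 names the column of L replicate 2, and its title was followed instead, since L replicate 2 carries the same line and the columns named for L replicate 3 hold other values.

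The authors deposited 1 table with an estimated count and a TPM value (a transcript abundance scaled to a fixed total) for each gene and library. The submitters' processing notes name FastQC 0.11.9, Trimmomatic 0.39, HISAT2 2.2.1, StringTie 2.1.4 and DESeq2 1.32.0, with no role or order, and they name a human and a mouse genome build. Which annotation was used and whether counting used strand are not given in the sources used here. The estimated counts deposited per gene were exactly equal to a whole number, with no tolerance, in 92.7% of cells, so they were rounded to whole numbers before testing. The TPM values deposited by the authors sum to the same total in each library, and were used for the filter, for the levels given in the text and for alternatives. Of 22013 entries in the table, 112 carry no symbol. Reads from near-identical gene copies may have been split or dropped by the counting, so values of multigene family members are uncertain, likewise those of overlapping genes.

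Genes with a TPM of at least 1 in at least 3 of the 9 libraries were tested, which left 12553. All 9 libraries entered a single fit of the edgeR quasi-likelihood model (edgeR 4.0.16 in R 4.3.3) on the rounded estimated counts, with TMM scaling and the segment as the only term. Contrasts were T minus C, L minus C and L minus T, and an F test covered all 3 segments. Tests were two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The written plan foresaw this model for whole-number counts and limma on log2(TPM + 1) for TPM alone. The deposited counts are estimates, a case that plan did not name, so edgeR was used on the rounded values and limma (limma 3.58.1) stands as an alternative. Standard errors were derived from the log2 fold change and the F statistic of each contrast. Fold changes come from counts and TPM values from transcript abundances, so for genes with several transcripts the ratio of TPM means need not equal the fold change, as for Hoxa3 and Pdgfb.

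A gene at 0 counts in all libraries of a segment has its fold change given as a lower bound against a floor of 3 counts over that segment. With 1 to 3 counts in a segment, the ratio of summed counts scaled to library size is given with its exact 95% counting interval. Such intervals and floors cover counting error only, since the reads carry no molecular identifiers.

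Gene lists were written from general knowledge: 48 lists with 1145 entries, of which 43 had at least 5 tested members. They cover positional genes, scar matrix, meningeal layers, signalling pathways, cell states, other cell types and RNA quality, and none was chosen on these samples. Each list was compared with all other genes by camera with a preset correlation of 0.01 on log2 CPM, counts scaled to library size (prior count 2). Camera with an estimated correlation and fry were run beside it. Benjamini-Hochberg adjustment ran over 43 lists and 3 contrasts, which makes 129 tests. Sample groups, the contrasts and their tests, the lists and the rule for named genes were fixed before the data were examined, and tests and alternatives chosen later are named as such where they are given.

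The rule for named genes took, per contrast and direction, the 10 with the largest log2 fold change. They had to pass the threshold, have a mean TPM of at least 1 in the higher segment and show no overlap of values between the segments. Clone-based, predicted and pseudogene symbols were left out. For each list it took up to 4 members past the threshold with the largest absolute change, or, where none passed, up to 2 with the largest mean TPM. Hox genes with a mean TPM of at least 1 in any segment are reported as counts by direction, with examples. Some genes that the rule names are not reported here.

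The procedure was tested on simulated counts for T against C, with the real means and library sizes of 12553 genes and 200 genes changed. The edgeR test recovered 61.2% of genes changed by a log2 of 0.5, 97.0% of those changed by 1 and 100% of those changed by 2, with 13 false calls. Limma, run there on log2(CPM + 1) and counted without regard to direction, recovered 59.7%, 97.0% and 100%, with 12 false calls. With only 200 genes changed, the simulation does not test the scaling when many genes change, as the 6409 called between T and C. In the simulated T against C, with 12553 genes and 43 lists, the shifted list was called by camera and 0 of the 40 lists sharing no members with it were called. The simulated genes varied independently of each other, so this does not test the preset correlation of 0.01 that camera used on the real data.

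Replicate libraries were compared by a chi-square statistic of their counts over genes with at least 20 counts in the pair. Depth was 15652554 to 25204301 estimated counts per library, and the common biological coefficient of variation was 0.0823. Alternatives covered DESeq2 1.42.0, limma with pseudocounts of 1 and 0.1, library totals, RLE factors, quantile and median scaling, no filter and a TPM minimum of 5, no abundance trend, a robust fit, the replicate number as a block, fits of 2 segments alone and leaving out each library. GC content and length per gene came from the GENCODE annotation of an earlier mouse build (GRCm38) by gene identifier, which covered 99.8% of tested genes, and no coordinates were used. The overlap of T and L against the shared C libraries was set beside 20 simulations of unchanged groups.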

Results

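The series asks how fibroblasts differ between segments of the spinal cord, in the context of scar formation after injury. Meningeal fibroblasts lie in the membranes around the cord (dura, arachnoid and pia) and can deposit collagen-rich scar tissue. Gene expression was measured in 9 libraries, 3 from each of the segments C, T and L. Injured tissue was not analysed here. Total estimated counts were 20081085, 19074159 and 25204301 in C, 16555231, 20282546 and 19331829 in T, and 16193269, 15652554 and 18853180 in L. Between 12057 and 12305 genes reached a TPM of 1 per library, and the 10 most abundant genes took 6.96% to 8.75% of counts. Replicate libraries differed by more than sampling noise in each of the 9 pairs, with a chi-square per degree of freedom from 3.77 for L replicates 1 and 2 to 20.4 for T replicates 1 and 2. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

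Fibroblast transcripts were abundant in each segment. Col1a2, a chain of type I collagen, had a mean TPM of 1118 ± 38.6 in C, 1124 ± 56.2 in T and 1684 ± 36.4 in L (SD, n = 3 per segment). Fn1 (fibronectin) stood at 4364 ± 75.9, 5658 ± 177 and 6907 ± 215 TPM, and Acta2 (smooth muscle actin, a myofibroblast marker) at 7784 ± 63.4, 4743 ± 288 and 6851 ± 333 TPM. Fn1, Acta2, Col1a1 and Col3a1 were chosen after their values were seen. By the edgeR quasi-likelihood F test, 7018 of 12553 genes (55.9%) differed among the segments at an adjusted p of 0.05, and 7921 did without T replicate 1. Between T and C 6409 genes differed, between L and C 6230, and between L and T 2019. Without T replicate 1, part of the pair that lay farthest apart, these counts were 6958, 6890 and 2437. Changes are given relative to the TMM scale, on which the median gene moved by 0.02 (log2) for T against C and by 0.01 for L against C. In limma on log2(TPM + 1), where scale and model both differ from the edgeR fit, the median gene moved by 0.13 and 0.10. There 4110 genes were higher and 2214 lower in T than in C, against 3240 and 3169 with edgeR. For L against C, that split was 3737 and 2246, against 3064 and 3166. A pseudocount of 0.1 gave 4094 and 2191 for T, and 3746 and 2229 for L. Median centring of log2(TPM + 1) left more genes lower than higher, 2491 higher and 3313 lower for T and 2282 and 3399 for L. Of 129 tests of gene lists by camera, 57 were called, and 19 were with an estimated correlation.

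Hox genes, transcription factors that mark position along the body axis, separated the 3 segments. Hoxc8 had 4.58 ± 0.564 TPM in C, 92.0 ± 2.498 in T and 78.0 ± 5.46 in L (SD, n = 3), an 18.3-fold rise from C to T (log2 4.19, SE 0.09). Hoxa7 rose 12.1-fold and Hoxc6 6.51-fold from C to T. Hoxc9 rose 45.8-fold from C to T and a further 2.44-fold from T to L, where it reached 50.8 ± 1.37 TPM. Hoxc10 was 17.9-fold higher in L than in T, at 39.3 ± 0.803 against 2.23 ± 0.476 TPM, and Hoxa10 was 22.6-fold higher. Hoxa11 and Hoxd10 had 0 counts in T and were at least 51.7-fold and 45.05-fold higher in L. Against C, where they had 1 and 2 counts, the ratios were 178 (95% counting interval 31.4 to 7069) and 77.4 (20.98 to 646.6). Hoxc5 rose 4.77-fold and Hoxa6 3.11-fold from C to T. Hoxd4 fell 2.38-fold from C to T and 4.603-fold from T to L, and Hoxb5 fell 2.48-fold and 1.39-fold. Hoxd3 fell 5.17-fold from C to T. From T to L it fell 3.62-fold, a call that ended without T replicate 3 (edgeR adjusted p = 0.0539) and on log2(TPM + 1) in limma (adjusted p = 0.38), with a range of 0.000258 to 0.38 over 23 alternatives. Hoxb13, of paralog group 13, had 1.61 ± 0.404 TPM in C and 0 counts in T, at least 28.8-fold lower.

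Of 30 Hox genes with a mean TPM of at least 1 in any segment, 14 rose and 9 fell from C to T, 13 rose and 12 fell from C to L, and 7 rose and 14 fell from T to L. Among the 21 tested members of paralog groups 1 to 8, 14 fell from T to L and 7 did not pass (18 fell adjusted over the list alone), with a camera adjusted p of 1.93e-10. Paralog groups 9 to 13 had 7 of 9 tested members higher in L than in T, the same count adjusted over the list alone, with a camera adjusted p of 1.08e-09. From C to L, 7 of the 9 rose and 1 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.000289). From C to T, groups 1 to 8 had 10 rises and 7 falls (10 and 8 adjusted over the list alone, camera adjusted p = 0.12), and groups 9 to 13 had 4 rises and 2 falls (4 and 2 adjusted over the list alone, camera adjusted p = 0.19). From C to L, groups 1 to 8 had 6 rises and 11 falls (7 and 11 adjusted over the list alone, camera adjusted p = 0.527).

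**Figure D1:**
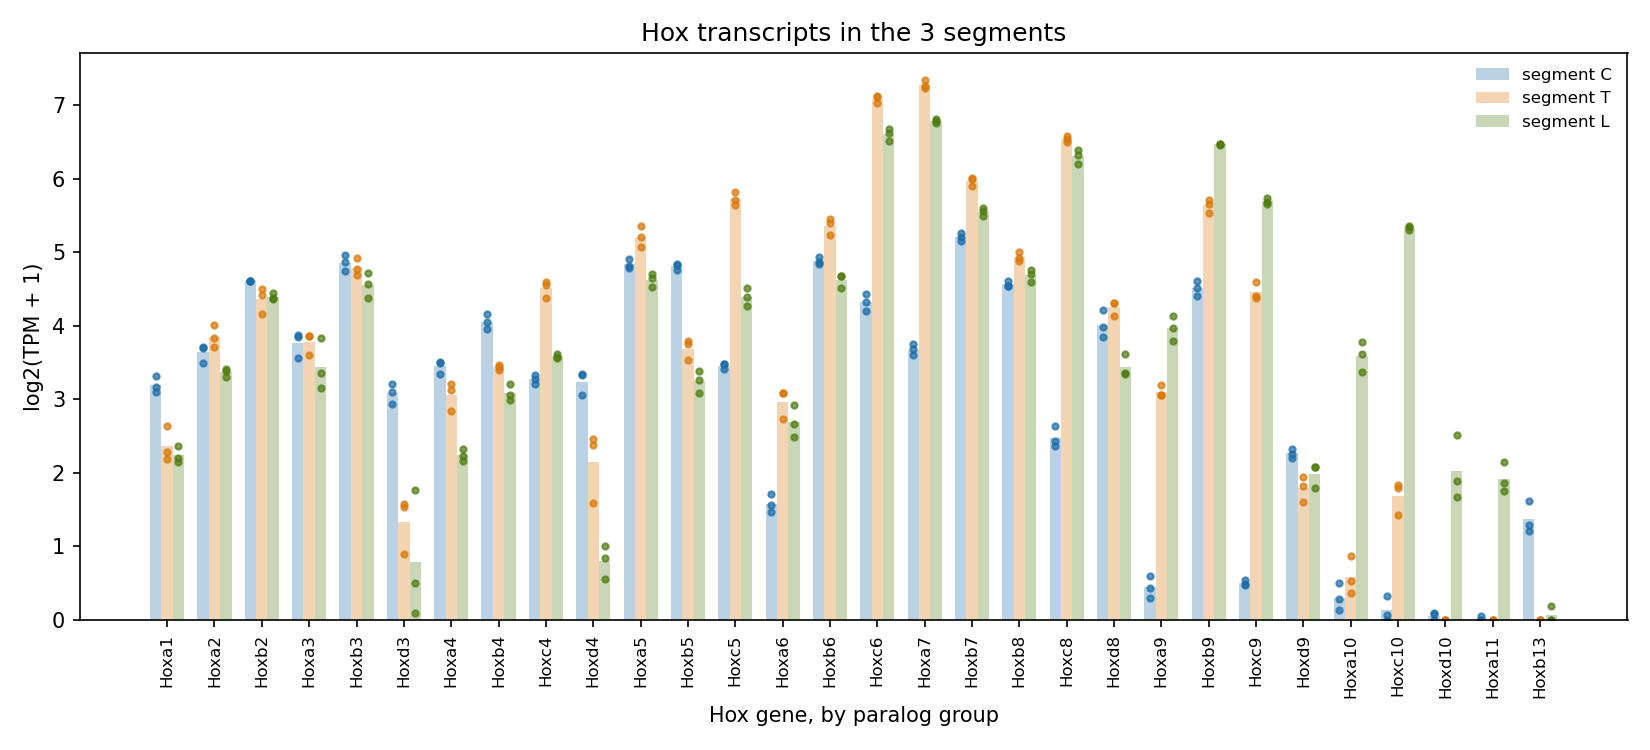
Expression of 30 Hox genes in segments C, T and L as log2(TPM + 1), with genes ordered by paralog group on the horizontal axis, bars for the mean of 3 libraries and dots for single libraries. Hoxc10 stands near 0.098 TPM in C, 2.23 in T and 39.3 in L.

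Segments T and C were compared for scar matrix and contractile transcripts. Tnc, Timp1 and Loxl2 were lower in T, while Col3a1 was higher and Col1a2 did not pass the test. Tnc, which encodes the matrix glycoprotein tenascin C, fell 16.7-fold (log2 fell by 4.06, SE 0.06, n = 3 per segment), from 839 ± 39.6 to 54.7 ± 0.805 TPM. Timp1, an inhibitor of metalloproteinases, fell 4.94-fold, and Loxl2, an enzyme that crosslinks collagen, fell 5.36-fold, from 786 ± 11.2 to 164 ± 2.57 TPM. In all, 3240 genes rose and 3169 fell, of which 743 and 906 did so by at least 2-fold.

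The contractile and myofibroblast list had 22 of 24 tested members lower in T and 2 higher, the same counts adjusted over the list alone (camera adjusted p = 1.27e-07, and adjusted p = 0.0837 with an estimated correlation). Des (desmin) fell 12.01-fold, Myh11 (smooth muscle myosin) 8.90-fold and Cnn1 (calponin) 5.37-fold, the last from 544 ± 17.8 to 111 ± 4.25 TPM. Acta2 fell 1.82-fold. The members that rose were Actg2, a smooth muscle actin, and Smtn (smoothelin), by 1.43-fold and 1.44-fold, both named after their values were seen. Mural cell markers, which share Acta2 and Myh11 with that list, moved with it: 7 of 10 fell and 1 rose (7 and 2 adjusted over the list alone, camera adjusted p = 0.00899, and adjusted p = 0.0909 with an estimated correlation). Mcam fell 10.99-fold and Anpep rose 5.08-fold. Basement membrane genes had 15 falls and 3 rises among 20 (15 and 4 adjusted over the list alone, camera adjusted p = 0.000289, and adjusted p = 0.13 with an estimated correlation). Laminin subunits led these, with Lamc3 7.47-fold and Lamb1 4.88-fold lower, while Lama3 was 5.65-fold higher at 1.42 ± 0.322 TPM.

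Collagen crosslinking and processing genes fell in 15 cases and rose in 6 of 22, the same counts adjusted over the list alone (camera adjusted p = 0.0179, and adjusted p = 0.48 with an estimated correlation). Matrix proteases and inhibitors had 15 falls and 8 rises of 26, also when adjusted over the list alone (camera adjusted p = 0.0392, and adjusted p = 0.338 with an estimated correlation). Their call also ended under quantile normalization (camera adjusted p = 0.0986) and without C replicate 1 (camera adjusted p = 0.054). Over 17 alternatives the adjusted p ranged from 2.74e-06 (fry) to 0.338 (camera). Adamts15, a matrix protease, rose 5.30-fold. Fibrillar collagens and scar matrix moved both ways, with 15 rises and 12 falls of 32 (16 and 13 adjusted over the list alone, camera adjusted p = 0.828). Their median of 0.02 (log2), mean of -0.09 and camera direction (up) differ in sign, and the median turns to -0.00486 with median centring. Fbn2 (fibrillin) rose 22.98-fold to 23.1 ± 0.955 TPM, Col3a1 rose 2.33-fold to 2667 ± 76.3 TPM, Col15a1 fell 14.5-fold and Postn (periostin) 4.99-fold. Col1a1 fell 1.52-fold, and Col1a2 had a log2 change of -0.12 (edgeR adjusted p = 0.122).

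Markers of the meningeal layers moved in different directions between T and C. Arachnoid markers had 8 rises and 2 falls of 13 (9 and 2 adjusted over the list alone, camera adjusted p = 0.00481, and adjusted p = 0.0717 with an estimated correlation). Cldn11, a tight junction protein of the arachnoid barrier, rose 93.3-fold from 1.10 ± 0.316 to 111 ± 4.37 TPM. Cdh1 (E-cadherin) rose 39.8-fold and Wnt6 22.6-fold, while Aldh1a2, a retinoic acid synthesizing enzyme, fell 8.75-fold. Cdh1 is also on the list of epithelial markers, of which Krt15 and Krt19, keratins named after their values were seen, rose 34.7-fold and 2.16-fold beside it. Dura markers had 11 rises and 3 falls of 14, the same counts adjusted over the list alone (camera adjusted p = 0.000396). Ccn3, a matricellular protein, rose 21.1-fold to 814 ± 78.6 TPM, Gja1 (connexin) rose 4.22-fold, and Mgp (matrix Gla protein) fell 4.81-fold. Pia and perivascular fibroblast markers had 9 falls and 3 rises of 14 (9 and 4 adjusted over the list alone, camera adjusted p = 0.0165, and adjusted p = 0.116 with an estimated correlation). Spp1 (osteopontin) fell 7.40-fold and Ngfr 6.47-fold. Pan-fibroblast markers had 11 rises and 8 falls of 20, also adjusted over the list alone (camera adjusted p = 0.612), with Thy1 6.03-fold lower and Clec3b 7.38-fold higher in T.

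Among the largest changes, Agtr2, the type 2 receptor of angiotensin II, had 0 counts in C and was at least 343-fold higher in T, at 11.4 ± 2.498 TPM. Scara5, a ferritin receptor, rose 290-fold to 195 ± 6.54 TPM, and Slc4a10, a bicarbonate transporter, rose 206-fold to 117 ± 25.7 TPM. Prss35 rose 77.4-fold. Ptgdr, a prostaglandin D2 receptor with 1 count in C, was higher by a ratio of 424 (95% counting interval 75.6 to 16790). The transcription factor Tbx20 fell 116-fold from 19.3 ± 1.318 TPM. Folh1, a folate hydrolase, fell 116-fold. Cmklr2 and Nkx6-2 had 0 counts in T and were at least 66.9-fold and 18.0-fold lower, and Ivl (involucrin) was lower by a ratio of 186 (51.3 to 1544). Kng1, Prss42, Fbxw15 and Mup20 were also among the largest rises and Lce1h, Gzmd and Or51e2 among the largest falls, but they belong to multigene families, so their values are uncertain.

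Cell cycle genes were higher in T than in C, with 29 rises among 34 and 5 members not passing, the same counts adjusted over the list alone (camera adjusted p = 1.08e-09). Nusap1, a spindle protein, rose 2.84-fold and Top2a 2.23-fold, from 17.5 ± 2.58 to 42.6 ± 7.47 TPM. Replication-dependent histones, also a multigene family, went down in 6 of 14 and up in 1, also adjusted over the list alone (camera adjusted p = 0.0433, and adjusted p = 0.147 with an estimated correlation). Their call also ended under quantile normalization (0.0893) and without C replicate 2 (0.052) or T replicate 2 (0.062), as camera adjusted p. Over 17 alternatives the adjusted p ranged from 1.55e-05 (fry) to 0.147 (camera). H3c2 fell 17.4-fold. Interferon response genes rose in 21 of 28 and 7 did not pass (22 rose adjusted over the list alone, camera adjusted p = 1.07e-05), led by Ifit1 at 2.74-fold and Oasl2 at 2.31-fold. Chemokines and cytokines fell in 13 of 18 and rose in 1, the same counts adjusted over the list alone (camera adjusted p = 0.000538), with Il6 13.6-fold, Lif 6.80-fold and Il11 6.15-fold lower.

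Unfolded protein response genes fell in 16 of 22 and 6 did not pass, also adjusted over the list alone (camera adjusted p = 6.1e-05, and adjusted p = 0.0642 with an estimated correlation). Asns fell 2.78-fold and Ddit3 2.16-fold. Hypoxia and glycolysis genes had 22 falls and 3 rises of 28, the same counts adjusted over the list alone (camera adjusted p = 0.000116, and adjusted p = 0.255 with an estimated correlation). The lactate transporter Slc16a3 fell 9.34-fold, but Egln3, a hypoxia-induced prolyl hydroxylase, rose 13.7-fold and Ndrg1 5.15-fold. Growth factors and neurotrophins had 18 falls and 10 rises of 32, also adjusted over the list alone (camera adjusted p = 0.0184, and adjusted p = 0.154 with an estimated correlation). Pdgfb, a platelet-derived growth factor chain, fell 17.4-fold, and Pgf (placental growth factor) rose 6.21-fold. In the TGF-beta pathway 14 fell and 8 rose of 29, also adjusted over the list alone (camera adjusted p = 0.14), and its median of -0.11 turns to 0.06 under quantile normalization. Tgfbi fell 6.69-fold and Tgfb2 6.001-fold. In the BMP pathway 9 fell and 7 rose of 22, also adjusted over the list alone (camera adjusted p = 0.746), with Gdf6 31.0-fold lower and Gdf10 7.87-fold higher.

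Markers of other cell types differed between T and C beside these groups. Schwann cell markers fell in 11 of 13 and rose in 2, the same counts adjusted over the list alone (camera adjusted p = 3.56e-05). L1cam fell 9.13-fold and Erbb3, a neuregulin receptor, 8.41-fold, from 11.7 ± 1.12 to 1.51 ± 0.277 TPM. Oligodendrocyte lineage markers fell in 5 of 9 and rose in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.00767, and adjusted p = 0.116 with an estimated correlation), with Sox10 8.38-fold lower. Endothelial markers fell in 5 of 8 and rose in 3, also adjusted over the list alone (camera adjusted p = 0.127), led by Emcn at 33.2-fold and Flt1 at 15.5-fold lower. They were called on log2(TPM + 1) (camera adjusted p = 0.018) and log2(TPM + 0.1) (0.0411). Over 17 alternatives the adjusted p ranged from 6.05e-07 (fry) to 0.265 (camera). Neuronal markers fell in 4 of 6 and rose in 1, also adjusted over the list alone (camera adjusted p = 0.053), with Stmn2 13.04-fold lower. Without C replicate 1 or 3, L replicate 1 or T replicate 1 they were called (camera adjusted p = 0.0415, 0.0402, 0.0471 and 0.0439). They were also called by camera on log2(TPM + 1) (0.0118), on log2(TPM + 0.1) (0.0153) and with library totals (0.0312). Over 17 alternatives their adjusted p ranged from 4.81e-07 (fry) to 0.175 (camera). Astrocyte and ependymal markers rose in 6 and fell in 5 of 12, also adjusted over the list alone (camera adjusted p = 0.75), and their median (0.34) and mean (-0.24) differ in sign. Macrophage markers rose in 4 and fell in 4 of 17, also adjusted over the list alone (camera adjusted p = 0.828), and their median of 0.12 turns to -0.07 with median centring. For mitochondrially encoded transcripts the camera adjusted p was 0.489 and for cytosolic ribosomal proteins 0.148, and quantile normalization moves their medians from -0.14 to 0 and from -0.10 to 0.10. Ribosomal proteins were called downward without T replicate 1 (camera adjusted p = 0.0158, range 0.0158 to 0.821 over 17 alternatives).

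Comparing L with C, the matrix genes Tnc and Timp1 were lower in L, while Eln and Tnmd were higher. Tnc fell 11.8-fold (log2 fell by 3.56, SE 0.06, n = 3 per segment), from 839 ± 39.6 to 76.7 ± 3.66 TPM. Timp1 fell 3.97-fold to 623 ± 19.7 TPM. Eln (elastin) rose 6.41-fold, from 21.6 ± 0.908 to 151 ± 8.47 TPM, and Tnmd (tenomodulin) rose 9.99-fold, from 25.2 ± 2.52 to 272 ± 16.5 TPM. In all, 3064 genes rose and 3166 fell, with 699 and 870 doing so by at least 2-fold.

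Fibrillar collagens and scar matrix had 16 rises and 10 falls of 32 (17 and 11 adjusted over the list alone, camera adjusted p = 0.144). Fbn2 rose 9.48-fold, Col3a1 1.95-fold and Col1a2 1.40-fold, Col15a1 fell 8.94-fold, and Col1a1 had a log2 change of -0.12 (edgeR adjusted p = 0.184). Basement membrane genes fell in 13 of 20 and rose in 2, also adjusted over the list alone (camera adjusted p = 0.000895, and adjusted p = 0.155 with an estimated correlation), with Lamc3 5.91-fold and Lama1 4.56-fold lower. Contractile genes fell in 17 of 24 and rose in 2 (18 and 3 adjusted over the list alone, camera adjusted p = 0.00121, and adjusted p = 0.224 with an estimated correlation). Des fell 2.93-fold, Myh11 2.39-fold, Cnn1 2.14-fold and Acta2 1.25-fold, while Actg2, named after its value was seen, rose 2.098-fold. For mural cell markers, 6 fell and 1 rose of 10 (6 and 2 adjusted over the list alone, camera adjusted p = 0.0954). They were called on log2(TPM + 1) (camera adjusted p = 0.0459), and over 17 alternatives the adjusted p ranged from 1.71e-05 (fry) to 0.223 (camera). Crosslinking genes fell in 12 and rose in 4 of 22, also adjusted over the list alone (camera adjusted p = 0.0559), with Tgm2 3.31-fold lower and P4ha2, a collagen prolyl hydroxylase subunit, 2.66-fold higher. Crosslinking genes were called without L replicate 3 (camera adjusted p = 0.0337) or T replicate 1 (camera adjusted p = 0.0493), on log2(TPM + 1) (0.0465) and on log2(TPM + 0.1) (0.0437). Over 17 alternatives their adjusted p ranged from 0.00129 (fry) to 0.568 (camera). Proteases and inhibitors fell in 13 and rose in 7 of 26, also adjusted over the list alone (camera adjusted p = 0.137), with Adamts15 8.99-fold and the collagenase Mmp13 5.57-fold higher. The TGF-beta pathway had 15 falls and 6 rises of 29, also adjusted over the list alone (camera adjusted p = 0.0185, and adjusted p = 0.377 with an estimated correlation), led by Eng (endoglin) at 4.56-fold and Fst (follistatin) at 4.47-fold lower.

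Arachnoid markers rose in 9 of 13 and fell in 2, also adjusted over the list alone (camera adjusted p = 0.00811, and adjusted p = 0.0837 with an estimated correlation). Cldn11 rose 32.3-fold to 37.8 ± 2.99 TPM and Wnt6 14.5-fold. Dura markers rose in 8 of 14 and fell in 4, also adjusted over the list alone (camera adjusted p = 0.0234, and adjusted p = 0.119 with an estimated correlation). Ccn3 rose 8.28-fold, Gja1 4.95-fold, and Penk (proenkephalin) fell 5.98-fold. The dura call also ended with camera on log2(TPM + 1) (adjusted p = 0.0616) or log2(TPM + 0.1) (adjusted p = 0.0652). Over 17 alternatives its adjusted p ranged from 1.17e-07 (fry) to 0.119 (camera). Pia and perivascular markers fell in 11 of 14 and rose in 3, also adjusted over the list alone (camera adjusted p = 0.000396). Spp1 fell 9.98-fold and the chemokine Cxcl12 fell 5.00-fold, from 63.0 ± 2.66 to 13.1 ± 1.49 TPM. The retinoic acid list had 9 falls and 5 rises of 16, also adjusted over the list alone (camera adjusted p = 0.0929), and among them Aldh1a1 fell 11.5-fold and Rarb, a retinoic acid receptor, 10.8-fold, while Rbp4, a retinol carrier, rose 22.4-fold to 5.89 ± 0.634 TPM.

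Agtr2 was at least 396-fold higher in L than in C, and Scara5 was 128-fold higher. The posterior Hox genes Hoxc10, Hoxa11, Hoxc9 and Hoxd10 made up 4 of the 10 largest rises, with Hoxc10 365-fold and Hoxc9 112-fold higher. The transcription factor Tbx20 fell 127-fold. The pioneer factor Foxa1 and the neural factor Sox21, each with 1 count in L, were lower by ratios of 126.8 (95% counting interval 22.4 to 5040) and 109 (19.2 to 4324). Gdf6, a BMP ligand, fell 69.1-fold. Ivl was lower by a ratio of 112 (38.1 to 545.8) and Alkal1, an ALK ligand, by 81.9 (14.4 to 3267), while Clec4n, a lectin of myeloid cells, was at least 13.4-fold lower. Fbxw15, Mup20, Prss42, Kng1, Lce1g and Prl2c3 complete the largest changes and belong to multigene families, so their values are uncertain.

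Cell cycle genes rose in 33 of 34 with 1 not passing, also adjusted over the list alone (camera adjusted p = 3.5e-14). Cenpf rose 3.99-fold, Mki67 3.46-fold from 5.55 ± 2.24 to 20.8 ± 2.62 TPM, and Ccnb2 3.37-fold. Histones fell in 8 of 14 with 6 not passing (10 fell adjusted over the list alone, camera adjusted p = 0.00121, and adjusted p = 0.0532 with an estimated correlation), with H3c2 10.4-fold lower. Interferon response genes rose in 26 of 28, the same count adjusted over the list alone (camera adjusted p = 3.26e-09), with Ifit1 4.22-fold and Gbp2 2.78-fold higher. Chemokines and cytokines fell in 13 of 18 and rose in 3, also adjusted over the list alone (camera adjusted p = 0.0011), with Il6 5.02-fold and Lif 4.45-fold lower. Growth factors fell in 19 of 32 and rose in 6 (19 and 7 adjusted over the list alone, camera adjusted p = 0.00565, and adjusted p = 0.116 with an estimated correlation), including Fgf10 at 6.32-fold lower. Unfolded protein response genes fell in 12 of 22 (13 adjusted over the list alone, camera adjusted p = 0.00496, and adjusted p = 0.138 with an estimated correlation), with Asns 2.39-fold lower. Hypoxia and glycolysis genes fell in 19 of 28 and rose in 2, also adjusted over the list alone (camera adjusted p = 0.00248, and adjusted p = 0.376 with an estimated correlation). Hk2 (hexokinase) fell 3.13-fold while Egln3 rose 7.25-fold and Ndrg1 3.26-fold.

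Other cell types and RNA measures moved with segment L as well. Macrophage and microglia markers fell in 14 of 17 with 3 not passing, also adjusted over the list alone (camera adjusted p = 3.42e-05, and adjusted p = 0.0532 with an estimated correlation). C1qc fell 3.81-fold, C1qb 3.44-fold, and C1qa 2.48-fold from 15.2 ± 0.746 to 6.56 ± 0.262 TPM. Astrocyte and ependymal markers fell in 9 of 12 and rose in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 0.00181, and adjusted p = 0.0642 with an estimated correlation). Gfap fell 5.08-fold, from 75.2 ± 5.93 to 15.9 ± 0.861 TPM, and Foxj1 15.0-fold, while Gjb6, a connexin, rose 33.5-fold, from 0.148 ± 0.0829 to 5.69 ± 0.880 TPM. Schwann cell markers fell in 11 of 13 and rose in 2, also adjusted over the list alone (camera adjusted p = 0.00354, and adjusted p = 0.0652 with an estimated correlation), with Cadm4 3.42-fold lower. Neuronal markers fell in 4 of 6 (5 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.0134, and adjusted p = 0.113 with an estimated correlation), with Stmn2 7.81-fold and Tubb3 4.12-fold lower. The Y-linked transcripts Eif2s3y, Uty, Kdm5d and Ddx3y, named after their values were seen, were 3.39-fold, 3.47-fold, 3.29-fold and 2.70-fold higher in L. Nuclear encoded respiratory chain genes fell in 12 of 29 (11 adjusted over the list alone, camera adjusted p = 0.0283, and adjusted p = 0.568 with an estimated correlation), a call also absent without L replicate 2 (camera adjusted p = 0.0976, range 0.00953 to 0.568 over 17 alternatives). Cytosolic ribosomal proteins had a camera adjusted p of 0.049 downward and an adjusted p of 0.762 with an estimated correlation, and their median of -0.14 turns to 0.06 under quantile normalization. That call ended without C replicate 2 (0.124), L replicate 1 (0.0831), L replicate 2 (0.266) or T replicate 3 (0.0526), as camera adjusted p. It also ended with camera on log2(TPM + 1) (0.191), on log2(TPM + 0.1) (0.184) and with library totals (0.0876). The camera adjusted p lay in a range of 0.00597 to 0.948 over 17 alternatives.

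**Figure D2:**
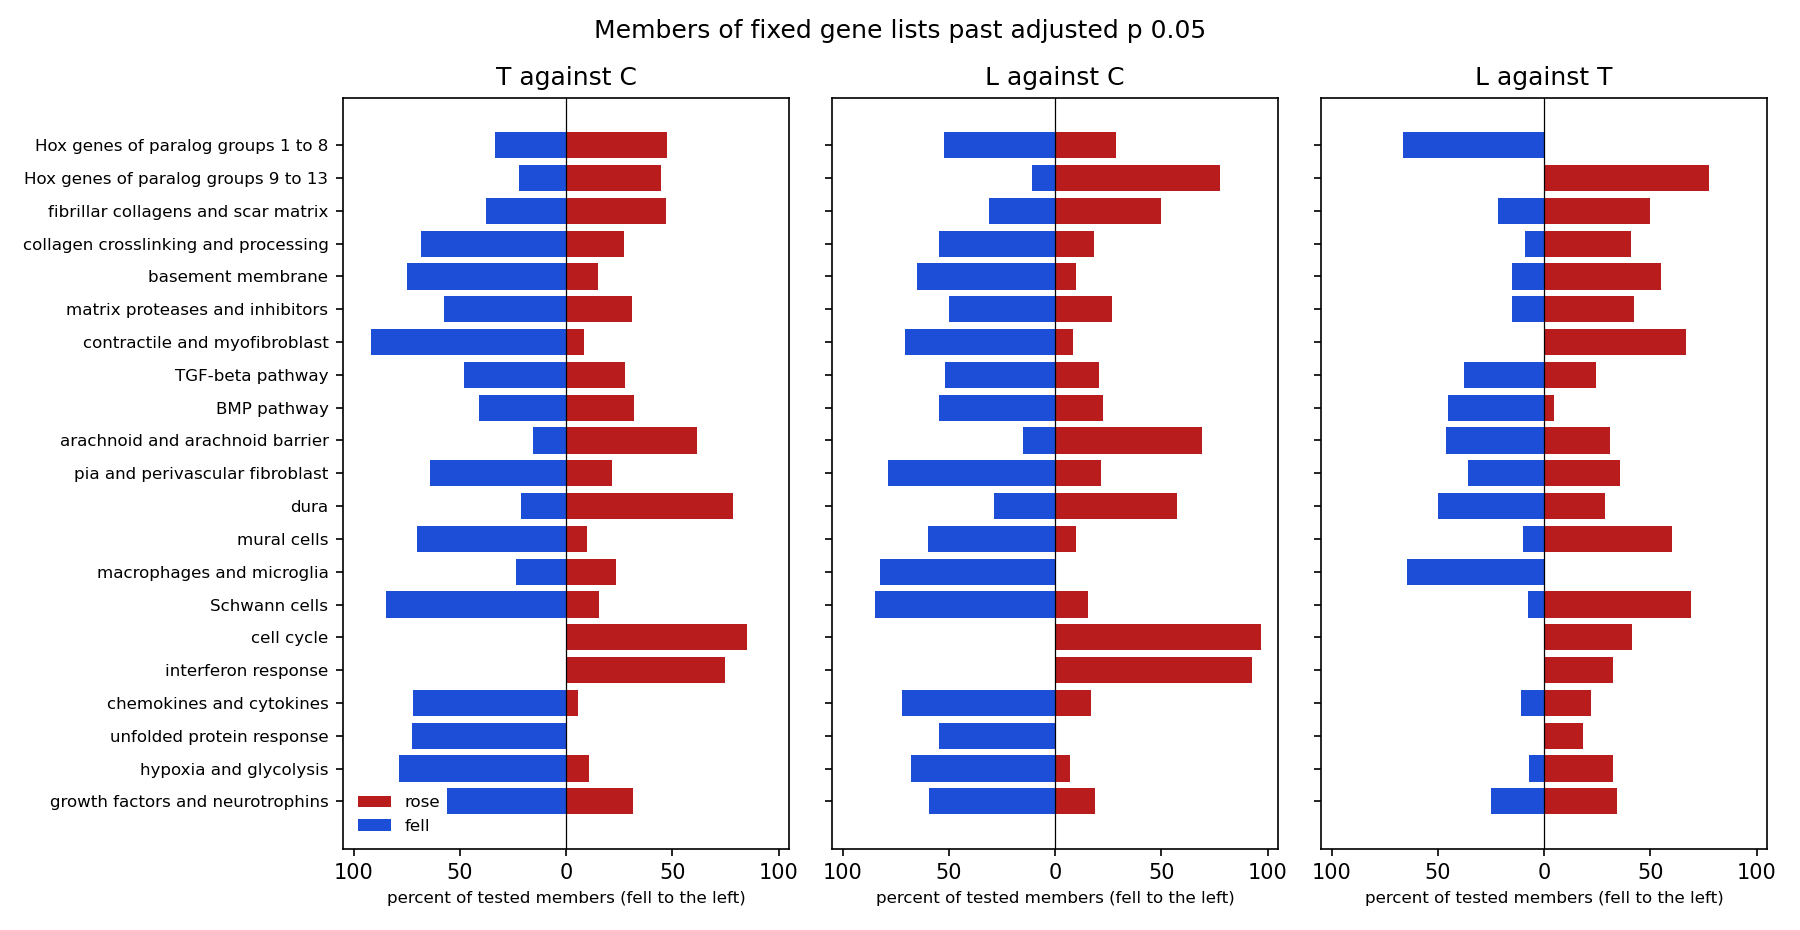
Percent of the tested members of each of 21 gene lists that rose (right of 0) or fell (left of 0) at an edgeR adjusted p of 0.05, for T against C, L against C and L against T. The medians of fibrillar collagens, the TGF-beta pathway and macrophages for T against C change sign under another scaling.

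Segments L and T differed least in number of genes, and contractile and several matrix transcripts were higher in L. Cnn1 rose 2.504-fold (log2 1.324, SE 0.06, n = 3 per segment), from 111 ± 4.25 to 273 ± 6.91 TPM, and Loxl2 rose 2.23-fold, from 164 ± 2.57 to 357 ± 7.25 TPM. Eln rose 2.55-fold and Postn 2.34-fold. Acta2 rose 1.46-fold and Col1a2 1.52-fold, while Col3a1 fell 1.20-fold. In all, 989 genes rose and 1030 fell, 231 and 310 of them by at least 2-fold. An offset for GC content and length, chosen after seeing the data, called 3334 genes in place of 2019.

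Contractile genes rose in 16 of 24 with 8 not passing (20 rose and 2 fell adjusted over the list alone, camera adjusted p = 4.29e-09, and adjusted p = 0.0652 with an estimated correlation). Des rose 4.09-fold, Myh11 3.72-fold and Itga11, a collagen receptor subunit, 2.62-fold. Mural cell markers rose beside them in 6 of 10 and fell in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 1.14e-05), with Rgs5 3.79-fold and Mcam 2.29-fold higher. Fibrillar collagens and scar matrix rose in 16 of 32 and fell in 7 (16 and 8 adjusted over the list alone, camera adjusted p = 0.0338, and adjusted p = 0.369 with an estimated correlation). That call also ended under quantile normalization (camera adjusted p = 0.102) and without T replicate 3 (camera adjusted p = 0.059). Over 17 alternatives the adjusted p ranged from 0.00026 (fry) to 0.369 (camera). Fbn2 fell 2.42-fold and Fbln1 (fibulin) rose 2.31-fold. Crosslinking genes rose in 9 of 22 and fell in 2 (11 and 3 adjusted over the list alone, camera adjusted p = 0.00715, and adjusted p = 0.44 with an estimated correlation). Basement membrane genes rose in 11 of 20 and fell in 3, also adjusted over the list alone (camera adjusted p = 0.00471, and adjusted p = 0.221 with an estimated correlation), with Col18a1 2.18-fold higher and Lama3 5.61-fold lower. Proteases and inhibitors rose in 11 of 26 and fell in 4 (12 and 4 adjusted over the list alone, camera adjusted p = 0.0228, and adjusted p = 0.288 with an estimated correlation). Mmp13 rose 2.59-fold, Mmp2 2.06-fold from 154 ± 8.04 to 311 ± 12.2 TPM, and Mmp12 fell 3.11-fold.

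The BMP pathway was lower in L, with 10 falls and 1 rise of 22 (11 and 1 adjusted over the list alone, camera adjusted p = 1.59e-05). Gdf10 fell 5.41-fold and Bmp6 4.55-fold, from 17.7 ± 0.427 to 3.83 ± 0.160 TPM, and the BMP antagonist Nog (noggin) fell 3.49-fold. Wnt pathway genes fell in 14 of 37 and rose in 6 (17 and 7 adjusted over the list alone, camera adjusted p = 0.0185, and adjusted p = 0.136 with an estimated correlation), with Wnt10a 7.86-fold lower and Wnt10b 4.95-fold higher. Cldn11 fell 2.89-fold, Cdh1 4.05-fold and Ccn3 2.54-fold, and Tnmd rose 3.24-fold. Arachnoid, dura and pia lists were not called, with camera adjusted p of 0.678, 0.078 and 0.277. Cell cycle genes rose in 14 of 34 with 20 not passing (16 rose adjusted over the list alone, camera adjusted p = 7.28e-07), with Cenpf 3.88-fold and Mki67 3.40-fold higher. Interferon response genes rose in 9 of 28 (10 adjusted over the list alone, camera adjusted p = 0.000542), with Stat2 1.60-fold and Ifit1 1.54-fold higher. Unfolded protein response genes rose in 4 of 22, also adjusted over the list alone (camera adjusted p = 0.00323, and adjusted p = 0.126 with an estimated correlation), with Calr (calreticulin) 1.31-fold higher. Hypoxia and glycolysis genes rose in 9 of 28 and fell in 2 (11 and 3 adjusted over the list alone, camera adjusted p = 0.0387, and adjusted p = 0.519 with an estimated correlation), with Slc16a3 4.17-fold higher. The hypoxia call also ended without L replicate 3 (0.119), T replicate 2 (0.0841) or T replicate 3 (0.0526), as camera adjusted p in a range of 0.0136 to 0.519 over 17 alternatives.

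Beyond the Hox genes, Gata3 rose 10.8-fold from T to L, Folh1 9.35-fold, Cpa6, a carboxypeptidase, 6.66-fold from 1.83 ± 0.131 to 12.1 ± 0.885 TPM, and Nrgn (neurogranin) 6.25-fold. Riiad1 and Dbil5, with 3 counts each in T, were higher by ratios of 8.13 (95% counting interval 2.44 to 42.4) and 7.75 (2.32 to 40.6). Their edgeR calls ended when any of 4 libraries was left out. For Riiad1 these were L replicates 1 and 2 and T replicates 2 and 3 (edgeR adjusted p = 0.104, 0.101, 0.0816 and 0.112), in a range of 0.0111 to 0.112 over 22 alternatives. For Dbil5 they were L replicates 1 and 3 and T replicates 1 and 3 (edgeR adjusted p = 0.107, 0.129, 0.072 and 0.108), in a range of 0.0127 to 0.129. Foxa1 was lower in L by a ratio of 96.6 (17.0 to 3850) and Folr2, a folate receptor of macrophages, by 19.9 (6.50 to 98.75). Dio3, which inactivates thyroid hormone, fell 14.5-fold, from 6.62 ± 1.12 to 0.489 ± 0.154 TPM. Slc4a10 fell 10.4-fold, the anion transporter Slc26a7 10.2-fold, Ctxn3 13.3-fold, Bend5 8.47-fold, the potassium channel Kcnj10 7.81-fold and the tetraspanin Tspan8 7.50-fold.

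Markers of other cell types differed between L and T in both directions. Macrophage markers fell in 11 of 17 with 6 not passing (15 fell adjusted over the list alone, camera adjusted p = 1.32e-10). Lyz2 (lysozyme) fell 3.15-fold, from 228 ± 2.097 to 71.3 ± 2.31 TPM, and Csf1r 2.94-fold. Astrocyte and ependymal markers fell in 7 of 12 and rose in 2, also adjusted over the list alone (camera adjusted p = 0.000542), with Gfap 6.59-fold and Aqp4 6.12-fold lower and Gjb6 3.32-fold higher. Schwann cell markers rose in 9 of 13 and fell in 1 (11 and 1 adjusted over the list alone, camera adjusted p = 2.68e-08), with Cdh19 4.26-fold and L1cam 3.80-fold higher. Oligodendrocyte lineage markers rose in 4 of 9 and fell in 1 (5 and 2 adjusted over the list alone, camera adjusted p = 0.00899, and adjusted p = 0.119 with an estimated correlation), with Sox10 3.46-fold higher. Endothelial markers rose in 3 of 8 with 5 not passing (5 rose adjusted over the list alone, camera adjusted p = 0.00496, and adjusted p = 0.0782 with an estimated correlation), with Esam 4.72-fold higher. Mitochondrially encoded transcripts rose in 9 of 13 with 4 not passing (10 rose adjusted over the list alone, camera adjusted p = 0.00121, and adjusted p = 0.44 with an estimated correlation), with mt-Nd6 1.87-fold and mt-Nd5 1.49-fold higher.

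**Figure D3:**
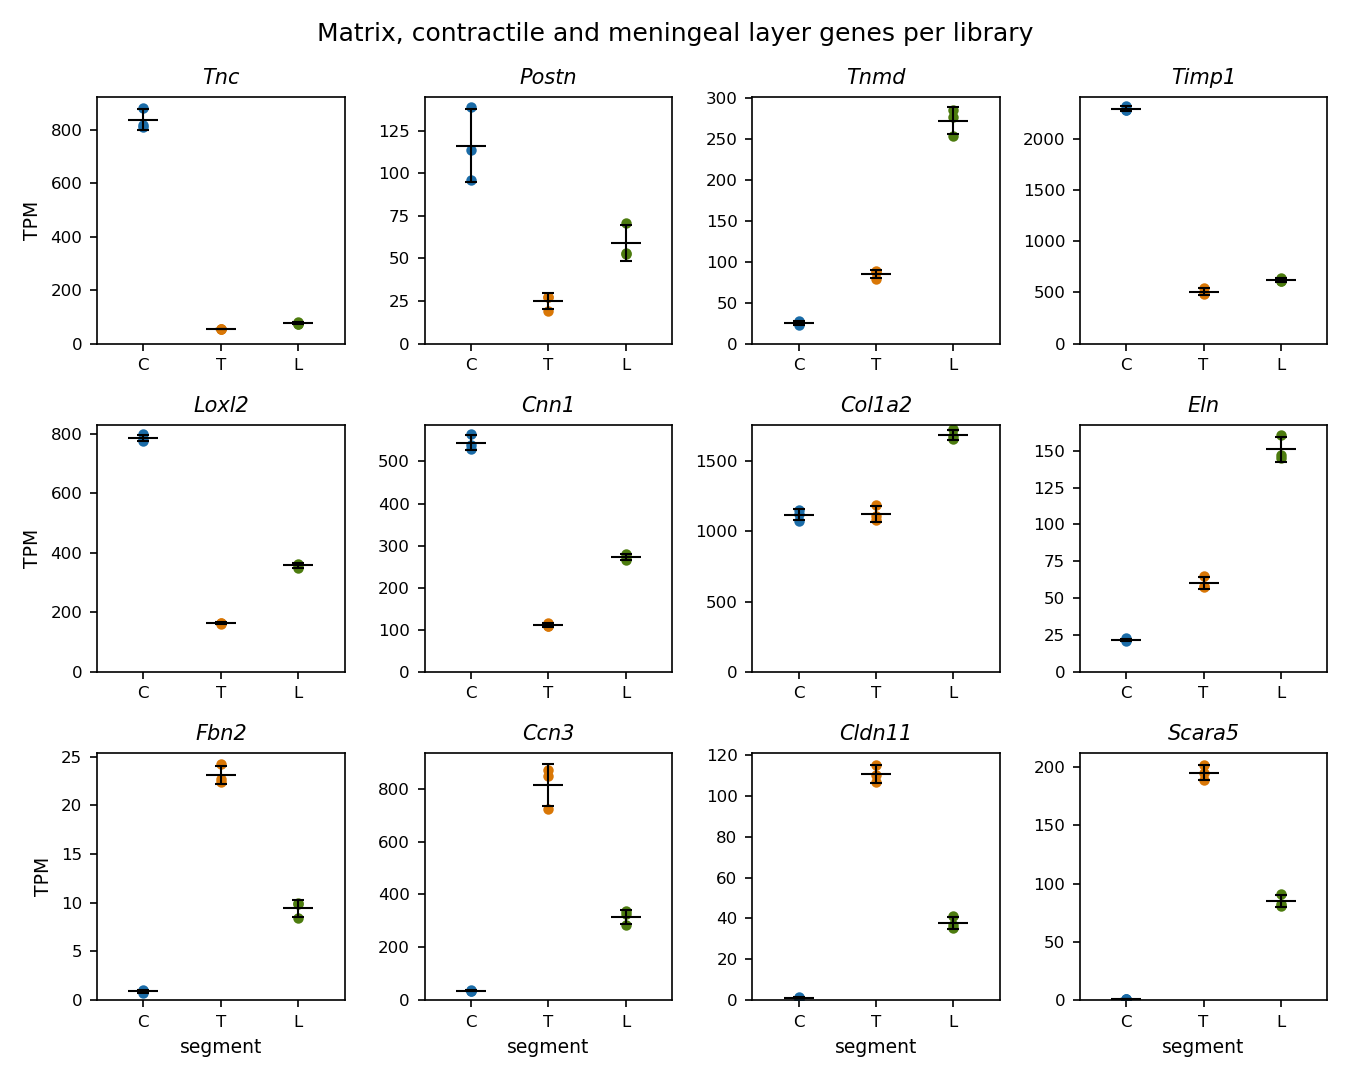
TPM per library of 12 genes in segments C, T and L, with dots for single libraries and bars of mean ± SD over 3 libraries. Tnc falls from 839 TPM in C to 54.7 in T and 76.7 in L, while Cnn1 stands at 544, 111 and 273 TPM.

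Across the 3 comparisons 13 lists were not called by camera at its preset correlation on log2 CPM, with adjusted p from 0.0559 to 0.99. They were retinoic acid, limb and segment transcription factors, pan-fibroblast markers, skeletal muscle, cartilage and bone, adipocytes, senescence and p53 targets, complement, antigen presentation, axon growth inhibition and guidance, immediate early and dissociation response, sterol and fatty acid synthesis, and imprinted growth genes. Camera under other settings called 3 of them. Antigen presentation in L against C was called without C replicate 1 (camera adjusted p = 0.0446) or L replicate 2 (0.0297), on log2(TPM + 1) (0.0477) or log2(TPM + 0.1) (0.0453) and under quantile normalization (0.0443), in a range of 0.00136 to 0.384 over 17 alternatives. Complement in L against T was called without L replicate 1 (camera adjusted p = 0.0422), on log2(TPM + 1) (0.042) and on log2(TPM + 0.1) (0.0497), in a range of 0.000752 to 0.185. Retinoic acid in L against C was called on log2(TPM + 1) (camera adjusted p = 0.026) and log2(TPM + 0.1) (0.0411), in a range of 1.72e-06 to 0.301. The low end of each range comes from fry, which does not compare a list with other genes. Median, mean and camera direction differed in sign for adipocytes in each comparison, for imprinted genes in T against C and L against T, for sterol synthesis in T against C, for immediate early genes in L against C, and for cartilage and for axon guidance in L against T. The lists of lymphocytes and granulocytes, erythroid cells, epithelial cells, nuclear RNA and sex chromosome transcripts had too few tested members for camera.

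Genes that differed from C in T and in L overlapped. Both segments were higher than C in 2376 genes and lower than C in 2492, and 94 genes went in opposite directions. In 20 simulations all 9 libraries, C included, were drawn from means shared by the segments, and the overlaps averaged 0.05, 0.1 and 0. Almost no gene is called when no segment differs, so these values do not show what changed segments sharing C would give. Independent lists of these sizes would share 790.8, 799.3 and 1591. Part of the excess may come from the shared C libraries, which are too few to be split. Scara5, Agtr2, Kng1, Prss42, Fbxw15 and Mup20 were among the 10 largest rises in both comparisons, and Tbx20 and Ivl among the 10 largest falls.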

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

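Library totals without TMM, RLE factors, the GC and length offset and camera on log2(TPM + 1) were chosen after seeing the data, and the other alternatives were planned. Counts of differing genes stayed within 1.5 times the reported ones except in 2 kinds of setting. A fold of at least 2 left 1649 genes between T and C, 1569 between L and C and 541 between L and T, by construction. The GC and length offset gave 3334 between L and T, and the cause was not tested. Leaving out each library gave 5451 to 6958 genes between T and C and 5221 to 6890 between L and C. Between L and T it gave 1412 to 2437 genes, and 5882 to 7921 among the 3 segments. Called list tests, each a list in a comparison, numbered 54 to 61. Each of the highest values came without T replicate 1. The labels do not say whether replicate numbers pair the libraries. Of 9 pairs of equal number, 3 correlated above 0.1, over a range of -0.148 to 0.291. Of the 9 libraries, 4 correlated best with their own number, which does not settle whether they were paired. With the replicate block, 6252, 6084 and 1892 genes differed in the 3 comparisons, 6858 among the segments, and 60 list tests were called. The block added antigen presentation, the BMP pathway and mitochondrially encoded transcripts in L against C and neuronal markers in T against C, and it left out hypoxia and glycolysis in L against T. Of named genes it ended the calls of Dbil5, C1s1, Dlk1 and Pdgfb in L against T. Of the 57 list tests called by camera, 19 were called with an estimated correlation, and that adjusted p was the highest of 17 alternatives for 56 of the 57. Fry, which tests a list's own genes and not against other genes, called 100 of the 129 list tests. Its direction was opposite to that of camera, with adjusted p from fry, for fibrillar collagens (0.0245), the BMP pathway (0.000774), limb and segment transcription factors (0.00129) and imprinted genes (0.00628) in T against C, Hox groups 1 to 8 (1.05e-05) and limb and segment transcription factors (0.00253) in L against C, and axon guidance (0.0273) in L against T. Under quantile normalization, ribosomal proteins in L against C turned upward (camera adjusted p = 0.948) and Rps2 in T against C turned to a log2 change of 0.06907, and the cause was not tested. Of 531 results on named genes, 55 lost their call in at least 1 of 23 alternatives, and 44 did when a library was left out. Over the other values of genes and lists, 11810 and 2042 kept their side of the threshold with no called direction reversed, 268 and 66 fell short of it, and 77 of lists moved past it. Values that were called in neither setting could change sign and still count as kept. Depth limits genes with few counts: those at 0 in a segment have lower bounds only, and those with 1 to 3 counts have wide counting intervals.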

Other observations

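The tests of Y-linked transcripts, Schwann cell and astrocyte markers and the term enrichment were chosen after the results were seen, as were the genes Krt15, Krt19 and Dsp, while the tests of depth, GC content, abundant genes and splits of the libraries were written before. Terms of the deposited annotation were tested among genes that changed at least 2-fold, by a hypergeometric test with Benjamini-Hochberg adjustment over 9474 tests, of which 214 were called. The hypergeometric test treats genes as independent draws and leaves out correlation between genes, so its p-values cannot be set beside those of camera. Cell adhesion took 54 of its 262 genes among the falls from C to L, where 18.1 would fall by chance (hypergeometric adjusted p = 1.93e-09). From C to T it was enriched on both sides, with 54 genes among the falls against 18.9 by chance and 47 among the rises against 15.5 (hypergeometric adjusted p = 5.08e-09 and 1.09e-08). It was also enriched on both sides from T to L. Mitotic sister chromatid segregation took 15 of 28 genes among the rises from C to L, with 1.55 by chance (adjusted p = 7.59e-09 in that test). Receptor signalling through G proteins took 34 of 149 genes among the falls from C to T, with 10.7 by chance (hypergeometric adjusted p = 9.27e-07). Extracellular matrix organization was enriched on both sides from C to T, with 26 of 97 genes among the falls against 6.99 by chance and 21 among the rises against 5.73 (hypergeometric adjusted p = 1.62e-06 and 5.96e-05).

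Of 4 tested members of the epithelial list, Krt15, Krt19 and Cdh1 had their highest mean in T. Krt15 had a mean TPM of 0.149 in C, 5.83 in T and 1.12 in L, and Krt19 had 26.3, 61.8 and 33.3 (n = 3 per segment). Cdh1, which is in the epithelial list and in another list, had 0.14, 6.04 and 1.46 TPM. Dsp (desmoplakin), the fourth, had 6.52 TPM in C, 6.11 in T and 2.965 in L.

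Segment C stood apart, since the smaller of its counts against T and L was 3.09 times the count between L and T. Library depth is argued against, since this ratio was 3.12 after thinning each library to the smallest total. The 50 most abundant genes are argued against in the same way, with a ratio of 3.1 without them. Removing trends with GC content and length lowered the ratio to 2.25, so these trends are argued against only as the whole account of it. The 10 splits of 6 libraries are too few for a share under 0.05: 1 of 10, the real one, gave as many genes in each comparison, with 6409, 6230 and 2019 genes by edgeR and a highest other count of 0 (unadjusted p under 0.05: 7154, 6998 and 3401 genes in the real split and up to 1127, 317 and 2920 in the others; limma: 6324, 5983 and 1679, and up to 0, 0 and 1). Among 100 drawn splits of the 9 libraries 1, the real one, reached 7018 genes by the F test and the highest other 5116. A share of 1 in 100 is the smallest that these splits can give. It argues against a random division of the libraries only if they are independent, which the labels do not say. A difference in dissection or preparation between segments, for which the labels give no batch, and a biological difference between segments were not tested.

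Y-linked transcripts were lowest in C and highest in L, with Eif2s3y at 14.1, 32.8 and 51.8 TPM in C, T and L. Reads shared with X-linked copies are argued against, since the smallest difference of log2 changes within the 4 pairs was 1.4 (SE 0.253). A different share of male cells or animals may account for the pattern and stays open: 1 of 4 X-linked partners was lower in L, and their median change was 0.03 (log2) with a largest SE of 0.127. No female-specific transcript was among the 4 tested members of the sex chromosome list, which has 6 entries. Sex is not given in the sources used here.

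Schwann cell markers were highest in C and lowest in T, and 84.6% of 13 tested members were lower in T. This share restates the pattern, so it does not test whether the share of Schwann lineage cells differed, which stays open, as does a change of these genes within the labelled cells. The exceptions were S100b and Prx, which rose, and 3 of the 13 are also in another list. The most abundant member, Pmp22, which fibroblasts also express, had 179.5, 130.5 and 168.7 TPM in C, T and L.

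Astrocyte and ependymal markers were lower in L than in T for 58.3% of 12 members, while 2 members, Gjb6 among them, were higher.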
